A study of Drosophila melanogaster with 2 samples.

How the data were processed

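Chromatin immunoprecipitation followed by sequencing was done on whole adult male Drosophila melanogaster carrying the transcription factor toe (twin of eyegone) with green fluorescent protein fused to its C-terminus. The protein was recovered with an antibody against the fluorescent tag, and chromatin was sheared by sonication, per the labels. The labels give 1 group with 2 biological replicates, numbered 2 and 3. A control experiment is named in the labels but is not analysed here. With 1 group there was no comparison between conditions, so the comparisons made were between replicates, between peaks and the annotated genome, and between peak sequences and other sequences of the same genome.

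The deposited data were 8 peak lists, 4 on each of the genome builds dm6 and dm3. Per the files' notes, regions were called on each replicate's alignments and on both replicates' alignments pooled, each against a control. A list of peaks reproducible between replicates was then derived by the irreproducible discovery rate. Each replicate list and each pooled list held exactly 30000 regions, peaks and background together. All 3469 reproducible peaks on dm6 were in the dm6 pooled list, and they were the 3469 regions with the highest signal in it. The aligner, the peak caller and their versions are not given in the sources used here.

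The deposited signal value of each peak is the authors' own, and its scale is not given in the sources used here. It was used to rank, filter and describe peaks within a list, and to correlate replicates across peaks, not to compare levels between lists. The deposited column read as −log10 of the q-value follows the usual layout of this file type, since the files have no header naming it. It served only to count regions with a q-value under 0.05. The lists carry no read counts, so the depth of each replicate is unknown, and intervals cover the counting of peaks, genes or windows only. No region had the same coordinates in both replicates' dm6 lists (0 regions), so they were treated as separate libraries.

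Coordinates are on dm6 and counted from 1. Genes, transcripts and start sites came from Ensembl release 115 (BDGP 6.54), without transposable elements, and sequence from the RefSeq copy of the same assembly. All dm6 regions lay on the chromosomes 2L, 2R, 3L, 3R, 4, X and Y and within their lengths. dm3 lists were used only for counts, overlaps and correlations within dm3, and no coordinates were converted. A summit within 500 bp of an annotated start site was called a promoter peak, and a gene with such a summit was called bound. Other summits were assigned in the order 5′ UTR, 3′ UTR, coding exon, other exon, intron and intergenic. Of the 2289 promoter peaks, 964 (42.1%) lay within 500 bp of start sites of more than 1 gene, so a peak can count for several genes. Some reproducible peaks overlap each other, and the 3469 peaks merge into 3225 regions. Overlapping peaks were each counted, and a word near several summits was counted once for each. Tests and intervals treat these counts as independent.

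Overlap between the replicates' strongest regions (at least 1 bp) was tested against 1000 circular rotations of a list within each chromosome (one-sided; the smallest possible p is 0.000999). The promoter share was tested against 1000 rotations of the summits (two-sided; the smallest possible p is 0.0020), and expected shares of the other classes came from 100 rotations. Chromosome shares were tested with two-sided exact binomial tests against length and, where named, against the share of start sites. Fixed gene lists (21) were tested with two-sided Fisher's exact tests against all other protein-coding genes, or against all other genes for transfer RNA genes, on members that could be matched. Symbols Dl, rye, caud and Z4 matched no gene and were left out. Fixed motifs (18) and all 8192 7-mers were searched on both strands in windows of 100 bp either side of the summit. They were compared by Fisher's exact test with 5 random windows per peak from the same chromosome, with the same promoter state, with a GC share within 2 percentage points and outside reproducible peaks. Shares of G and C were 37.6% in the peak windows and 37.7% in the controls. Benjamini-Hochberg adjustment was applied within each family of tests, and 0.05 was the threshold. Intervals on shares are 95% Wilson intervals, as drawn in the plots. Where no member of a list was bound, the limit printed in the text is 3 counts of the total, which differs from the upper Wilson bound. Ratios of central to flanking motif density have 95% exact binomial intervals.

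The gene lists covered retinal determination, Pax and Pax-like genes, phototransduction, notum and wing patterning, the JAK/STAT pathway, cytoplasmic and mitochondrial ribosomal proteins, oxidative phosphorylation, heat shock and chaperones, the circadian clock, innate immunity, muscle, neuron, glia, testis, male accessory gland, fat body and lipid metabolism, midgut, dosage compensation, insulator and architectural proteins, and transfer RNA genes. Genes were named by a fixed rule. It took the gene with the nearest start site for each of the 20 reproducible peaks with the highest signal, up to 4 members per list with the highest-signal promoter peak, and the retinal determination genes with or without a peak. It also took each motif past the threshold and the 5 enriched 7-mers with the smallest adjusted p. A gene that the rule takes is not reported here. Groups, tests, lists, motifs, the naming rule and the first set of other settings below were fixed before the data were examined.

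The first set of other settings changed the promoter window (200 bp and 1000 bp), the start sites (protein-coding genes only), the gene definition (gene body or 1000 bp upstream), the overlap rule (reciprocal overlap of at least 50%, or summits within 100 bp), the number of regions compared, the expected share of X, the summit window (50 bp either side), the control windows (1000 to 2000 bp from the summit) and the build. They also took the 1734 reproducible peaks with the highest signal, the same number of regions from the pooled list, and each replicate's own list in place of the reproducible list. The pooled setting turned out to hold the same peaks as the reproducible list, so it tested nothing. Settings chosen after seeing the data used the other regions of the pooled list as the expectation for promoters, 10000 random gene sets matched on the number of start sites, and peaks with no start site within 500 bp for motifs and 7-mers.

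The procedures were tested on simulated data. Uniformly placed summits were called in 3 of 100 simulated sets, and summits with 30% moved to start sites in 100 of 100. A gene list given 3-fold odds was called in 93 of 100 simulations, and unchanged lists in 6 of 2000 tests. Genes were bound independently in these simulations, while in the data 1 peak can count for several genes. The simulated rates therefore need not hold for the data. A 7-mer placed in simulated windows was called as a motif and ranked first among 8192 7-mers. The 8 others called in that simulation each shared at least 5 bases in a row with it. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.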

Results

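Binding of toe was mapped in whole adult male flies. toe and its neighbour eyg (eyegone) encode Pax-like transcription factors with a homeodomain and act in eye development. Chromatin from 2 biological replicates, numbered 2 and 3, was immunoprecipitated through the fluorescent tag on toe. On dm6 the authors' reproducible list held 3469 peaks with a median width of 420 bp and signal values from 58.2 to 3277.7 (median 102). Of these peaks, 3011 had a q-value under 0.05, so not all of them passed that threshold. Each replicate's own list held 30000 regions, of which 3437 in replicate 2 and 2467 in replicate 3 had a q-value under 0.05. Read depth is unknown.

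The strongest regions were largely shared by both replicates. Of the 3469 strongest regions of replicate 2, 2535 (73.1%, 95% interval 71.6 to 74.5%) overlapped one of the 3469 strongest of replicate 3. The regions at CG14100 and mRpL41 ranked 1 and 2 in both. Over the whole lists, including background, 13732 of 30000 regions of replicate 2 (45.8%) were shared, a share for which no rotation was run. Rotated lists shared 1.90% of the strongest regions on average (one-sided permutation p = 0.000999, the smallest that 1000 rotations can give).

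Of the reproducible peaks, 3447 (99.4%) overlapped a region of replicate 2 and 3417 (98.5%) a region of replicate 3. Across the 3395 peaks found in both, the log2 signal of the replicates correlated with Pearson's r = 0.82 and Spearman's rho = 0.756 (bootstrap 95% interval 0.736 to 0.774). These peaks were chosen for agreement between the same 2 replicates, so the overlaps and the correlation are not independent evidence of reproducibility. The correlation is also across peaks, which are not independent replicates.

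**Figure D1:**
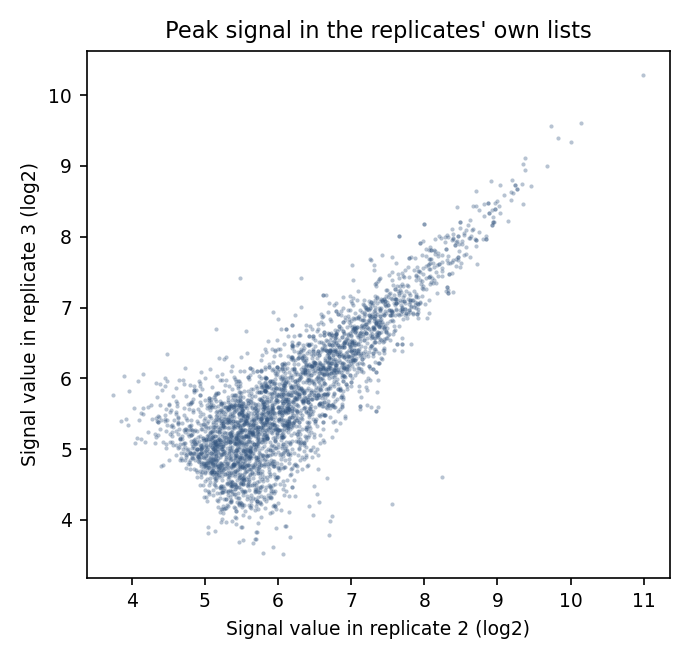
Signal value of each reproducible peak in replicate 2 (horizontal axis, log2) and in replicate 3 (vertical axis, log2), 1 point per peak, for the 3395 peaks overlapped in both replicates' own lists. Points follow a diagonal band, with Spearman's rho of 0.756.

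The highest peak lay at the promoter of CG14100, on chromosome 3L from 19590411 to 19590834, with a signal of 3277.7. It was followed by the promoter of mRpL41, a protein of the large mitochondrial ribosomal subunit (2R, 15217560 to 15217994, signal 1906). That summit also lay within 500 bp of a start site of lncRNA:CR44463. The promoter shared by asRNA:CR45928 and the translation factor gene eIF6 (2R, 23850220 to 23850577) came next with a signal of 1670. Of the 20 highest peaks, 15 had a summit within 500 bp of a start site and 18 had a protein-coding gene as the nearest. All 20 were among the 23 strongest regions of replicate 2 and the 26 strongest of replicate 3.

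Other promoter peaks among the 20 were nearest to Tcs5, Pdrg1, the UDP-galactose transporter gene Ugalt, the tubulin acetyltransferase gene Atat, CG31145 and Sox14. Further ones were nearest to Art3, the mitochondrial protease gene Lon, mRpL23, CG5611, CG7601 and lncRNA:CR31044. Their signals ran from 949 at lncRNA:CR31044 to 1583 at Tcs5. Several of these summits also lay within 500 bp of a start site of another gene. They were those of Tcs5 (CHMP2B), Pdrg1 (Pal1), Atat (Shc), Art3 (mRpS10), Lon (PIG-F), mRpL23 (CG9004), CG5611 (Mtl) and CG7601 (CIA30). The remaining 5 summits lay in introns. They had CG11050 (1034 bp away, signal 1620), CG16753 (5717 bp, 1175), Trl (1515 bp, 1150), CG9663 (951 bp, 1038) and Lk6 (981 bp, 1038) as the genes with the nearest start site. Trl encodes the GAGA factor.

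Most reproducible peaks lay at promoters. The summit was within 500 bp of a start site in 2289 of 3469 peaks (66.0%, 95% interval 64.4 to 67.5%). Rotated summits reached 13.6% on average and 16.5% at most (two-sided permutation p = 0.0020, the smallest that 1000 rotations can give). Coding exons held 8 summits (0.231%) against 13.2% after rotation, introns 24.2% against 39.3% and intergenic sequence 7.49% against 27.3%.

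The promoter share was higher among stronger peaks. It was 49.0% (95% interval 43.8 to 54.2%) in the tenth of the peaks with the lowest signal and 83.0% (78.7 to 86.6%) in the tenth with the highest. The share depended on the window, falling to 49.9% with 200 bp against 6.17% after rotation. In all, 2701 of 13968 protein-coding genes (19.3%) had a promoter peak.

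**Figure D2:**
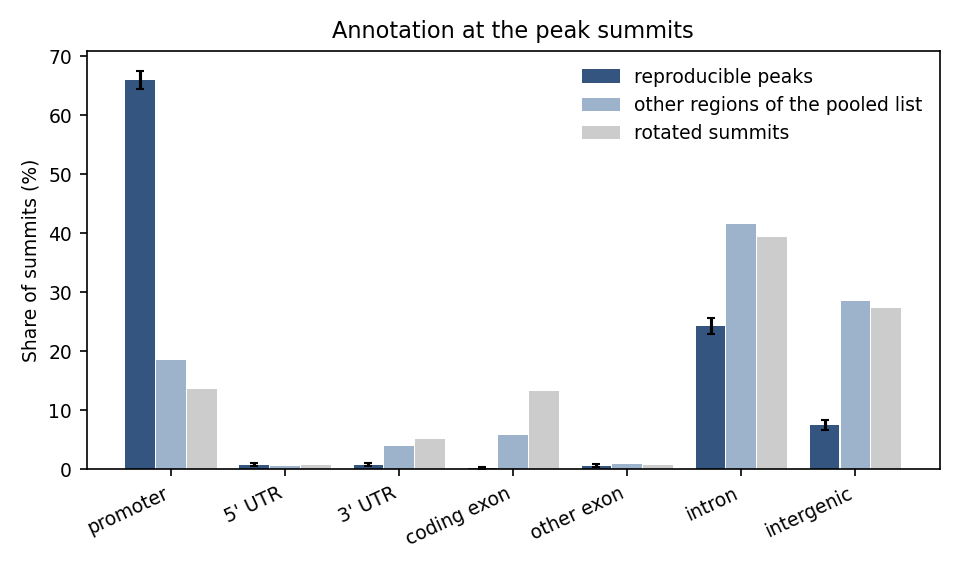
Share of summits (vertical axis, percent) in each annotation class for the 3469 reproducible peaks, the other 26531 regions of the pooled list, and summits rotated within chromosomes (mean of 100 rotations). Error bars are 95% Wilson intervals for the reproducible peaks, of which 66.0% lay at promoters, against 18.5% of the other regions.

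The genes toe and eyg lie on the minus strand of chromosome 3L, and both carried promoter peaks. At toe (12422510 to 12432668) the promoter peak ran from 12432608 to 12433027, with its summit 150 bp from the start site and a signal of 92.0. An intronic peak of toe had a signal of 84.1, and a pair of peaks 1327 bp and 2119 bp from its start site, in intergenic sequence, had signals of 83.0 and 160. At eyg (12462537 to 12468021) a single peak from 12467973 to 12468392 had its summit 162 bp from the start site and a signal of 224, ranking 582. Whether the tagged construct added copies of the toe region is not given in the sources used here.

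**Figure D3:**
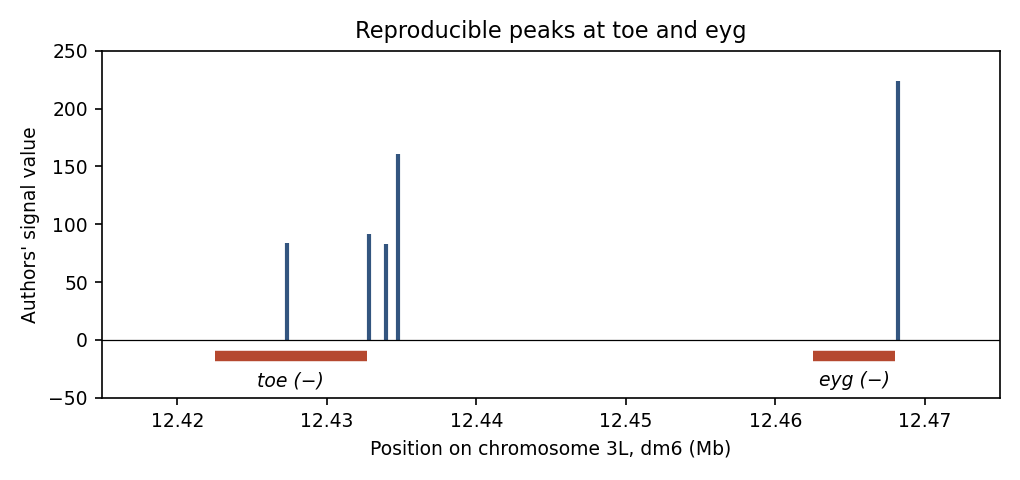
Reproducible peaks at toe and eyg on chromosome 3L (horizontal axis, dm6 position in Mb). Vertical lines stand at the summits with the authors' signal value as height, and bars below mark the genes; the highest line, 224, stands at the start of eyg.

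Of the 13 retinal determination genes, which specify the eye, 5 carried promoter peaks. These were eyg, toe, dac (signal 112, summit 496 bp from the start site), ey (101, summit 26 bp away) and so (59.2, 355 bp away). None of the 3469 strongest regions of either replicate had its summit within 500 bp of a start site of so. The nearest summit lay 3777 bp from a start site of hth, 5321 bp from tio, 6268 bp from gl, 9623 bp from toy, 10535 bp from eya, 13179 bp from ato, 16872 bp from Optix and 33649 bp from tsh. The share of bound members, 38.5% (95% interval 17.7 to 64.5%), was not distinguishable from the 19.3% of other protein-coding genes (Fisher's exact test, adjusted p = 0.285). Of the 10 Pax and Pax-like genes, 3 were bound, namely eyg, ey and toe (exact adjusted p = 0.586).

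Genes of both kinds of ribosome were bound more often than other genes. Of 93 cytoplasmic ribosomal protein genes, 55 (59.1%, 95% interval 49.0 to 68.6%) had a promoter peak, against 19.1% of the others (odds ratio 6.14, Fisher's exact test, adjusted p = 5.12e-16). Among the highest were RpS27 (signal 621), RpL32 (609) and RpL34b (487). Of 73 mitochondrial ribosomal protein genes, 30 (41.1%, 30.5 to 52.6%) were bound (odds ratio 2.93, exact adjusted p = 0.000123). They were led by mRpL41, mRpS10 (1022), mRpL23 (985) and mRpS23 (822). The mRpS10 peak is also that of Art3. Peaks named for RpS27, RpL32 and RpL34b also lay within 500 bp of start sites of Nup37, CG7943 and CG8132, in that order. Those of mRpL41, mRpL23 and mRpS23 likewise lay near lncRNA:CR44463, CG9004 and CenG1A.

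Of 14 circadian clock genes, 8 (57.1%, 32.6 to 78.6%) were bound (odds ratio 5.58, Fisher's exact test, adjusted p = 0.00797). They included the light sensor gene cry (signal 420, a peak also near lncRNA:CR46393), the transcription factor genes Pdp1 (134) and vri (127), and the kinase gene dco (130). Insulator and architectural proteins, which organise chromatin domains, had 8 of 15 genes bound (53.3%, 30.1 to 75.2%, odds ratio 4.78, exact adjusted p = 0.0101). The highest were Chro (808, a peak also near Ssl1), Cp190 (557, also near CG4338), Dref (319, also near RpL13) and pita (240). In fat body and lipid metabolism 9 of 18 genes (50%, 29.0 to 70.97%) were bound (odds ratio 4.18, exact adjusted p = 0.0101). Among them were the insulin receptor gene InR (212), the lipase gene bmm (209, a peak also near Tdrd3), Thor (115) and FASN1 (106).

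Against random gene sets with the same numbers of start sites, the calls for clock, architectural, and fat body and lipid genes ended (permutation adjusted p = 0.0872, 0.0510 and 0.155). Their matched shares were 26.3%, 21.6% and 26.7%, below the observed ones, so start site number was not shown to account for the excess. The calls for both ribosomal lists held (permutation adjusted p = 0.0020 each). The fat body and lipid call also ended without replicate 3 (exact adjusted p = 0.0845) and the clock and lipid calls ended with the 200 bp window (exact adjusted p = 0.617 and 0.317) and among the 1734 strongest peaks (exact adjusted p = 0.0859 and 0.523).

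Testis genes and transfer RNA genes were bound less often than other genes. None of 34 testis and spermatogenesis genes had a promoter peak (0%, which allows a share of up to 8.82%, or 3 counts of the total), against 19.4% of the others (Fisher's exact test, adjusted p = 0.00789). This call ended among the 1734 strongest peaks (exact adjusted p = 0.0740). Of 290 transfer RNA genes, 19 (6.55%, 4.23 to 10.01%) were bound, against 16.1% of other genes (odds ratio 0.367, exact adjusted p = 2.19e-05). Those with the highest signals were tRNA:Tyr-GTA-1-8 (553), tRNA:His-GTG-1-3 (275), and tRNA:Gln-TTG-1-2 and tRNA:Gln-TTG-1-3, which share a peak (267). These peaks also lay near start sites of CG8036, CG8490 and Spag1, in that order. Of the transfer RNA genes, 238 are identical in sequence to another, and 12 of these were bound, as were 7 of the 52 single-copy genes. Single-copy genes came closer to the 16.1% of other genes, but genes with identical copies make up most of the list. Whether identical copies account for the low share was not tested. Single-copy genes were not tested apart.

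No other list passed the test. Heat shock and chaperone genes had 8 of 22 bound, with Hsc70-5 (413), Hsp27 (346), Hsp83 (243) and Hsc70-4 (214) highest (exact adjusted p = 0.121). The Hsc70-5 and Hsc70-4 peaks were also near CG8531 and tefu. In oxidative phosphorylation 19 of 87 were bound, led by ND-MWFE (384), ND-51 (372), ND-SGDH (367) and ATPsynCF6 (266). These peaks were also near TppII, CG13994, RhoGAP68F and Sec13, in that order. In innate immunity 7 of 32 were bound, led by cact (497), imd (363, a peak also near Dp1), pll (246, also near TfIIA-L) and PGRP-LB (96.0).

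In muscle 4 of 27 were bound, namely Argk1 (311), Mef2 (117), Zasp52 (80.4) and Zasp66 (68.4). In neuron 3 of 22 were bound, namely elav (380), Csp (189) and Nrx-1 (113), and in glia 3 of 9, namely moody (355), Gli (80.8) and Gs2 (67.8). Phototransduction had 3 of 29 (rdgC, 233; rdgB, 164; Calx, 60.4), notum and wing patterning 2 of 21 (ush, 82.2; ci, 81.1) and the JAK/STAT pathway 2 of 10 (Ptp61F, 168; dome, 77.9). Peaks of elav, ush and ci were also near the non-coding genes lncRNA:enrr, lncRNA:CR46258 and asRNA:CR43957. Those of Ptp61F and dome were also near CG9166 and Ubqn. None of 20 accessory gland genes (exact adjusted p = 0.0564), 17 midgut genes (0.121) and 6 protein-coding dosage compensation genes (0.746) were bound. Taken as 3 counts of the total, these counts of 0 allow shares of up to 15.0%, 17.6% and 50%. The non-coding RNA gene lncRNA:roX1 of the dosage compensation list carried a peak (96.1), and lncRNA:roX2 had its nearest summit 8548 bp away. Among the 3469 strongest regions of replicate 3, none had its summit within 500 bp of a start site of Gs2, Ptp61F, ci, dco or dome. The same held in replicate 2 for Gli, Zasp66 and ush.

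**Figure D4:**
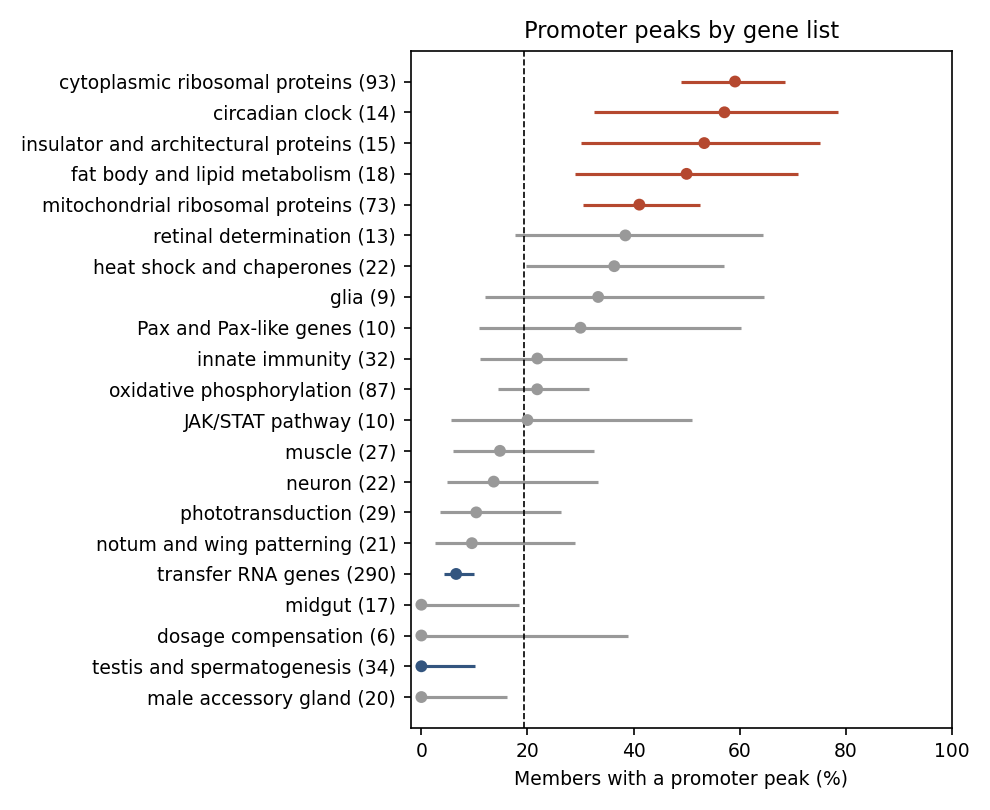
Share of members with a reproducible summit within 500 bp of a start site (horizontal axis, percent) for each gene list, with the number of members tested in brackets and 95% Wilson intervals as lines. The dashed line is the 19.3% of all protein-coding genes. Red lists were bound more often and blue lists less often at an adjusted p under 0.05, and grey lists did not pass.

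Chromosome 3R carried more peaks than its length predicts, and chromosomes 4 and Y fewer. 3R held 913 peaks (26.3%, 95% interval 24.9 to 27.8%, against 23.3% of length; exact binomial adjusted p = 0.000134). Chromosome 4, which carries ey and toy, held 16 peaks (0.461% against 0.980%, exact adjusted p = 0.00229), and Y held 0 (exact adjusted p = 2.55e-40). Against shares of start sites, 3R again held more (23.1%, exact binomial adjusted p = 4.34e-05), and 2R held fewer (17.7% against 20.5%, adjusted p = 7.36e-05). On that scale 3L held more (20.6% against 19.2%) and chromosome 4 fewer (0.772% of start sites), both narrowly (exact adjusted p = 0.0459 each). Y was still low (0.477% of start sites, exact adjusted p = 7.14e-07). How far reads map to Y was not tested, so its count of 0 does not by itself show less binding there. The X, of which males carry a single copy, held 580 peaks (16.7%, 15.5 to 18.0%), against 17.1% of length (exact binomial p = 0.558). The X share was below length among the 1734 strongest peaks (14.0%, exact p = 0.000397) and without replicate 3 (15.3%, exact p = 0.00518). Over all peaks it was not distinguishable from the 16.5% of start sites on X (exact p = 0.714), and was above the 14.7% that X takes of the bases in the pooled list (exact p = 0.00112).

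Sequences of promoter elements were more common at summits than in matched windows. The controls shared the promoter state of the peaks but not their distance from the start site, and lay outside reproducible peaks. Whether these elements are particular to toe, or common to promoters recovered with any factor, was not tested. The DNA replication-related element TATCGATA occurred in 5.04% of summit windows against 1.28% of controls (odds ratio 4.10, Fisher's exact test, adjusted p = 2.08e-37). The insulator core CGATA, part of the same sequence, occurred in 35.3% against 23.9% (odds ratio 1.74, exact adjusted p = 2.18e-41). Core promoter motif 1, GGTCACACT, occurred in 2.02% against 0.680% (odds ratio 3.01, exact adjusted p = 3.35e-11). GAGA repeats occurred in 5.19% against 2.13% (odds ratio 2.52, exact adjusted p = 4.26e-20). Within these peaks, GAGA repeats were less dense within 50 bp of the summit than at 150 to 250 bp (ratio 0.563, 95% interval 0.472 to 0.670), a comparison chosen after seeing the data.

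The E-box CAGCTG (10.8% against 6.57%, exact adjusted p = 3.04e-16) and the TATA box (34.3% against 30.3%, adjusted p = 1.50e-05) were also more common. The STAT site was less common (5.33% against 7.06%, exact adjusted p = 0.000407). The TATA box and STAT calls ended in windows of 50 bp either side (exact adjusted p = 0.698 and 0.263), and the E-box and STAT calls ended against windows 1000 to 2000 bp away (exact adjusted p = 0.758 and 0.262). The homeodomain core TAATTA occurred in 17.0% of summit windows and 15.5% of controls, which did not pass the test (odds ratio 1.12, exact adjusted p = 0.0632). It passed against the windows 1000 to 2000 bp away (odds ratio 1.66, exact adjusted p = 1.00e-20), where promoter state and GC share are not matched. The paired domain core GTCACGC occurred in 0.663% and 0.732% (exact adjusted p = 0.957). In the 1180 peaks with no start site within 500 bp, a set chosen after seeing the data, 2 motifs passed, GAGA repeats (odds ratio 2.90) and the TATA box (1.29).

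Of 8192 7-mers, 634 were more common at summits and 623 less common. The 7-mer with the smallest adjusted p, ACAGTGG, occurred in 7.38% of summit windows against 1.86% of controls (odds ratio 4.20, Fisher's exact test, adjusted p = 2.54e-52). It was followed by ATCGATA (10.7% against 3.82%), ACTATCG (6.51% against 1.75%), AGTGTTG (7.99% against 2.58%) and CTATCGA (7.70% against 2.49%). ATCGATA, ACTATCG and CTATCGA overlap the DNA replication-related element and were concentrated at promoters, where ATCGATA occurred in 15.1% of peaks against 2.12% elsewhere. ACAGTGG occurred in 5.90% of promoter peaks and 10.3% of other peaks. In the 1180 peaks away from start sites it had an odds ratio of 5.15 (exact adjusted p = 7.54e-29) and AGTGTTG 1.89 (adjusted p = 0.0236). ATCGATA, ACTATCG and CTATCGA did not pass there (exact adjusted p = 0.887, 0.368 and 0.696).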

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

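The dm3 list of reproducible peaks held 5 peaks on sequences outside the main chromosomes. They were noticed after the data were seen and belong to no comparison above. They lay on the heterochromatic sequences 2RHet, 3RHet and XHet and the unplaced sequences U and Uextra with signals from 62.0 to 96.5. The dm6 lists hold no sequences of these names, so no comparison between builds was made for them. Coordinates were not converted between builds, so where these sequences lie on dm6 was not tested.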

How the results depend on the processing

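No paired analysis was possible because there is only 1 group. The shared share and the promoter share kept their direction and side of the threshold under each setting chosen beforehand, and the counts of peaks and of motifs called stayed within 1.5 times. The motifs behind the count differed: the 50 bp window kept 5 of the 7, losing the STAT site and the TATA box, and windows 1000 to 2000 bp away kept 5 of the 7, losing the E-box CAGCTG and the STAT site, and called 10 in all. Taking the strongest regions of the pooled list changed nothing by construction. The X share (16.7%) was not distinguishable from its share of length or of start sites (16.5%, exact p = 0.714), although it lay below the former and above the latter, and was above that of bases in the pooled list (14.7%, exact p = 0.00112). It was 14.0% among the 1734 strongest peaks and 15.3 to 16.0% without either replicate. Those strongest peaks also gave a correlation of 0.784, 4 gene lists and 336 enriched 7-mers, the last 2 from fewer peaks, with the clock, testis, and fat body and lipid calls lost. The 50 bp window gave 262 7-mers and windows 1000 to 2000 bp away as controls 1371, of which 236 and 383 were among the 634. The cause of these shifts was not tested. Of the settings chosen after seeing the data, matching start site numbers left 3 gene lists, transfer RNA genes not tested, and the 1180 peaks away from start sites left 2 motifs and 214 7-mers. In those peaks core promoter motif 1 occurred in 0 of 1180 windows against 6 of 5900 controls (odds ratio 0, exact adjusted p = 0.828). The odds ratio there was 0.878 for ATCGATA and 0.732 for CTATCGA, which did not pass either. Without a replicate, 7 gene lists, 7 to 8 motifs and 614 to 667 7-mers passed (439 without replicate 2 and 465 without replicate 3 of the 634), the fat body and lipid call was lost without replicate 3, and the promoter share was 66.3 to 69.96%. Accessory gland genes passed as bound less often with 1000 bp, with gene bodies and without replicate 3, midgut genes with gene bodies, and heat shock genes as bound more often with 200 bp. Leaving out a replicate gives no count of reproducible peaks, shared share or correlation. Of 59 named genes with a promoter peak, 53 kept it without replicate 2, 55 without replicate 3, 46 among the 1734 strongest peaks and 40 with 200 bp. Depth is unknown, so its limit on weak peaks was not tested.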

Other observations

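Gene families defined by the letters that open their symbols, a grouping chosen after seeing the data, differed widely in promoter peaks. Among 76 families with at least 10 protein-coding genes, 16 passed Fisher's exact test after adjustment, 8 bound more often and 8 less often than other genes. Beside the ribosomal families, the glycosylphosphatidylinositol anchor genes PIG (12 of 21 bound, exact adjusted p = 0.0013), the peroxisome genes Pex (8 of 15, 0.0219), the Mediator genes MED (11 of 25, 0.0246) and the autophagy genes Atg (9 of 20, 0.0412) were bound more often. The number of start sites was not matched in these tests.

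Families of chemosensory and cuticle genes carried almost no promoter peaks. Gustatory receptors Gr had 0 of 60 bound (exact adjusted p = 5.87e-05), odorant receptors Or 0 of 59 (8.25e-05), ionotropic receptors Ir 1 of 60 (0.000602), odorant-binding proteins Obp 1 of 51 (0.00375), pickpocket channels ppk 0 of 28 (0.0219), cuticular proteins Cpr 0 of 70 (7.68e-06) and Osiris genes Osi 0 of 25 (0.0419). Histone genes His, which are repeated in the genome, had 2 of 115 bound (5.69e-07). Genes known only by a CG number were bound in 12.9% of cases, against 24.3% of the other protein-coding genes.

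The tests below were chosen after the patterns were seen. For the lower of the replicates' values and for the comparison with other 6-mers of A and T, what each outcome would mean was written before the value was computed, and for the others after it.

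A promoter share of 66.0% may have technical sources, and no biological explanation was tested. If rotation merely moved summits into gene-poor or unmapped sequence, other regions called on the same genome would match the peaks, but their promoter share was 18.5% (95% interval 18.1 to 19.0%). Recovery of open promoters by any immunoprecipitation stays open, since the share of 83.0% in the 347 strongest peaks is predicted both by that and by binding of toe. The hypothesis that toe itself brings these promoters predicts that the same antibody in flies without the tag would recover fewer of them. That control is not used here.

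ACAGTGG lay on 1 side of the summit. Read along the 7-mer, 340 of 419 occurrences within 150 bp (81.1%, 95% interval 77.1 to 84.6%) were upstream of the summit, by a median offset of -66 bp (exact binomial p = 1.18e-39, adjusted over 36 tests 2.13e-38), and the overlapping word TACAGTG gave 75.2%. Occurrences near overlapping peaks were counted once per summit, so this p-value treats repeated sites as independent. Promoter composition at annotated start sites as the only cause would give no side preference away from them, but there the share was 85.6% (80.0 to 89.8%). Those peaks were still richer in the TATA box than their matched windows (odds ratio 1.29), so promoter composition elsewhere stays open. Placement of summits in 1 library is argued against by the lower replicate share of 77.9% (73.3 to 81.8%). A candidate explanation that stays open is another DNA-binding protein at the same regions, as the nearer edge of the most common distance was 70 bp from the summit, a position seen before the test. It predicts that the protein that binds ACAGTGG would peak on the word itself, while the tagged toe peaks beside it.

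TAATTA, the homeodomain core, was denser at the summit than beside it, although it did not pass the test against matched windows. Its density within 50 bp of the summit was 1.61 times (95% interval 1.40 to 1.84) that at 150 to 250 bp, against 1.07 in the other regions of the pooled list, and TATCGATA had a higher ratio in the peaks, 1.89, while GAGA repeats had 0.563 and CAGCTG 0.847 (0.710 to 1.01). Core promoter elements at annotated start sites as the only cause are argued against by a ratio of 1.67 (1.31 to 2.12) in peaks with no start site within 500 bp. Those peaks were still richer in the TATA box than their matched windows (odds ratio 1.29), so core promoter elements elsewhere stay open. Placement in 1 library is argued against by 1.37 (1.19 to 1.57) as the lower replicate ratio. The content of A and T at the summit stays open, because TAATTA exceeded 97.1% of the 35 other 6-mers of A and T, but ATATTA had 1.62, the median of the others was 1.33 and the lower bound for TAATTA, 1.40, lies below several of them. The hypothesis that toe contacts TAATTA may be tested by its ratio in regions of an unrelated tagged factor without a homeodomain, where it predicts a value near that of the other 6-mers.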
